A study of Brassica juncea with 4 samples.

How the data were processed

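Leaf RNA of Brassica juncea (Indian mustard), cultivar RLM-198, was measured on 4 one-colour Agilent arrays of a Brassica napus oligonucleotide design: 2 from wild-type plants and 2 from transgenic BnCRY2aOE plants, all harvested 45 days after sowing. Per the labels, total RNA was extracted with a column kit for plant tissue, amplified, labelled with the dye Cy3 and hybridised 1 sample per array. Per the file headers, all 4 arrays lay on 1 slide, were scanned in 1 scan and were read with Agilent Feature Extraction 10.7.3.1, so neither slide nor scan separates the genotypes.

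Each deposited scanner file gives, per spot, a processed intensity, the raw median intensity of the spot and of its surroundings, and 0 or 1 marks for spots that are well above background, saturated or outlying. Per the file headers, Feature Extraction fitted spatial and multiplicative trends to each array on the way to the processed intensity. Judged from the values, spots at or below background carry a small positive stand-in value in it rather than a measured one. The deposited table of the whole series holds 43603 probes. Its scale and centring are not given in the sources used here. Judged from the deposited values, the authors made these log2 values from the processed intensity, scaled each array close to its 75th percentile and centred each probe on its median over the 4 arrays; the exact scaling stays unknown. The slope against the scanner values treated in that way was between 0.998 and 0.999 on every array, with r of at least 0.999. Its column medians were 0.05 and 0.00 for wild-type replicates 1 and 2, and -0.02 and -0.05 for BnCRY2aOE replicates 1 and 2. It was used as an alternative only.

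Starting from the deposited intensity values, control spots were left out, leaving 43803 spots for 43603 distinct probes. Spots marked as outliers (10 to 55 per array) were set to missing. No spot was saturated. The log2 processed intensity minus the array's 75th percentile is the level used throughout, and repeated spots of a probe were averaged. A probe was tested if it was well above background on both arrays of at least 1 genotype, which kept 29949 probes and left out 13654. Genotypes were compared per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all tested probes), with genotype as the only term and a threshold of an adjusted p under 0.05. Probes past it are referred to as called. This leaves 2 residual degrees of freedom per probe, to which eBayes added a prior worth 2.43. Where a probe was not well above background on either array of a genotype, its fold change is given as a bound. The bound sets the brighter genotype's mean against, on each array of the dimmer genotype, the higher of the probe's own level and the lowest level among probes well above background, averaged on the log2 scale.

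The fit was tested on simulated data drawn from the means of the 29949 tested probes and their spreads in shuffled order, with 200 probes changed. At a log2 change of 4 it recovered 70.5% of them with 2 false calls. At a log2 change of 1 or of 2 it recovered 0 of 200. The spreads drawn from were estimates with 2 residual degrees of freedom each, so their own error entered again, which can lower the recovery. Simulated probes were independent, and the shuffling removed any link between a probe's level and its spread. The 2 false calls therefore give no rate of false calls for the real data. The smallest change called in the real data was 1.87 on the log2 scale. With 2 arrays per genotype, the number of arrays limits the precision.

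The scanner files give each probe an ID and the identifier of a source sequence, and the value table the ID alone. Neither pairs them with a gene name or description, and no annotation table was used here. The 31 gene lists fixed before the data were examined, the tests of those lists and the report of cryptochrome probes were therefore not run. The level of the transgene was not analysed here, so the genotype labels were not checked by it. For the same reason the rule for named genes, also fixed before the data were examined, reduced to its fallback: probe IDs only, the 2 largest rises and the 2 largest falls, by fitted change, among probes past the threshold whose genotypes do not overlap. Probes with the same source sequence identifier were treated as probes of 1 sequence.

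Replicate numbers 1 and 2 occur in both genotypes, and nothing in the labels says that a number marks a shared plant, batch or day, so the main test has no replicate block. Alternatives were quantile and median scaling, normexp background correction, the authors' value table, 2 other filters on dim probes, kept outlier spots, intensity-trend and robust variance models, a replicate block, a looser threshold and leaving out each array. The planned normexp correction was run on the raw median intensity with an offset of 50, in place of the raw mean intensity, which was not used here. Further alternatives, added after the data were seen, were scaling by 8 spike-in controls, dim signals raised to the lowest level well above background, normexp fitted without spots marked as non-uniform or outlying, a crossed replicate block and removal of probes low on wild type replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from tables read with pandas 2.3.3.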

Results

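The study asked how the leaf transcriptome differs between Brassica juncea plants that overexpress BnCRY2a, a cryptochrome 2 gene of Brassica napus, and their wild type. Cryptochromes are blue-light photoreceptors of plants. Each genotype was represented by 2 arrays that the labels call biological replicates. The labels used here do not say how many plants or transgenic lines stand behind an array, so the p-values measure the spread between these samples only. The design of the array is that of a related species, so a probe's signal also depends on how well the B. juncea transcript matches it. The files do not pair the probes with gene names, and the level of the transgene was not analysed here.

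Between 67.5% and 71.4% of the 43603 probes were well above background on an array, 29420 and 30206 probes in wild type and 30100 and 31131 in BnCRY2aOE. The 75th percentile of the processed signal was 220 and 227 brightness units in wild type and 254 and 217 in BnCRY2aOE. Over the 29949 tested probes the wild-type replicates correlated at r = 0.978 and the BnCRY2aOE replicates at r = 0.966, across probes, which are not independent. The between-genotype pairs of arrays had r from 0.946 to 0.968.

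Most probes had signals within 2-fold in the leaves of the 2 genotypes, and a small set of probes differed strongly. In BnCRY2aOE leaves 59 probes were higher and 77 were lower than in wild type (limma, Benjamini-Hochberg adjusted p under 0.05), 0.454% of those tested. With bounds where a genotype was not well above background, the median change was at least 9.02-fold for the higher probes and 7.69-fold for the lower ones. Over all tested probes, 95.5% had a mean change under 2-fold and the median change was -0.02 on the log2 scale. At an unadjusted p under 0.05 (limma) there were 1903 probes, where 1497 would pass by chance on average. Probes are not independent, so a chance count can lie far from 1497, and the excess was not tested. A mean change of at least 2-fold was seen in 762 probes upward and 600 downward, most of which did not pass the test. For comparison, 960 probes differed at least 2-fold between the 2 wild-type arrays and 3263 between the 2 BnCRY2aOE arrays, and the 4 pairs of arrays across genotypes gave 1886 to 2974. A change of at least 2-fold in the same direction in all 4 pairings of a BnCRY2aOE with a wild-type array was found for 242 probes upward and 252 downward, 494 in all, where the other 2 ways to split the arrays into pairs gave 22 and 79. Each group of those 2 splits holds both genotypes, so their counts do not measure chance. The count of 136 was 32 without wild type replicate 1 (10 higher, 22 lower), and more probes were higher than lower without wild type replicate 2 (149 and 90 of 239), BnCRY2aOE replicate 1 (95 and 61 of 156) or BnCRY2aOE replicate 2 (119 and 102 of 221) and under spike-in scaling (94 and 85 of 179). It was 32 when only probes well above background on all 4 arrays were tested, 46 when dim probes were not filtered, and 1 or 62 after normexp background correction, depending on whether spots marked as outlying or non-uniform entered its fit. With a replicate block it was 38 (18 higher, 20 lower), 37 of them among the 136.

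**Figure D1:**
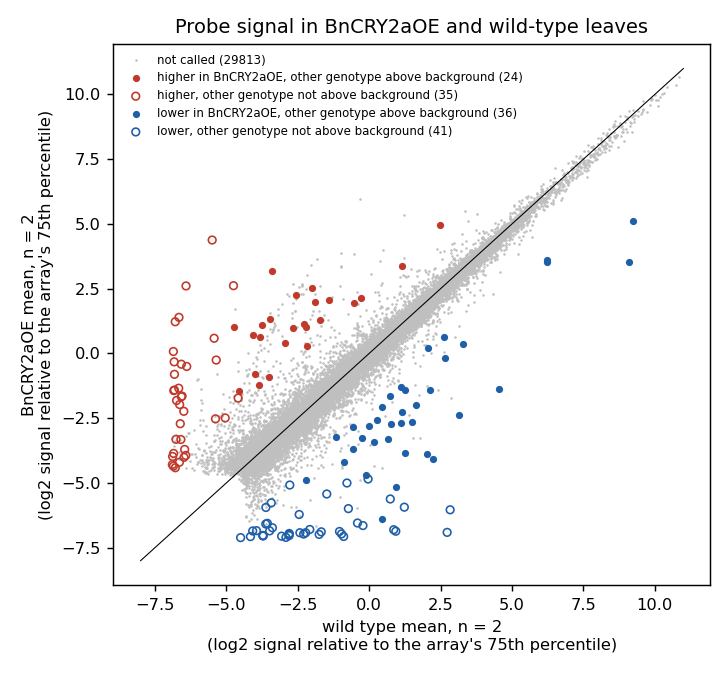
Each point is a tested probe, with its mean log2 signal (relative to the array's 75th percentile, n = 2 arrays) in wild type on the x axis and in BnCRY2aOE on the y axis; the line marks equal levels. The 59 higher probes (red) and 77 lower probes (blue) lie away from the line; open circles mark the 76 of them not well above background on either array of the other genotype, and filled circles were well above it on at least 1.

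Many called probes were well above background in a single genotype. Of the 136, 76 (55.9%) were not well above background on either array of one genotype: 35 higher probes in wild type and 41 lower probes in BnCRY2aOE. Among all tested probes this held for 556 (1.86%). The shares are not like for like: no change under 3.67-fold was called, while 95.5% of tested probes had a mean change under 2-fold. Where levels on the dim side are stand-in values, the p-values of the 76 calls rest in part on a spread that was not measured. Against the higher of a probe's own level and the lowest level well above background on each array, the median bound was 7.28-fold higher for the 35 and 5.16-fold lower for the 41. The 7.28-fold equals the fitted change of its probe, whose own wild-type levels lay above that lowest level. Of these bounds, 15 upward and 17 downward were 8-fold or more, and 13 were under 2-fold. The other 60 calls were well above background on at least 1 array of each genotype, and 53 of them on all 4 arrays. Among these 53, the median log2 change was 3.39 for the 22 higher and -3.11 for the 31 lower probes. In 62 of the 136 calls the brighter genotype was above the array's 75th percentile. Calls with one genotype not well above background were a minority, 51 of 112, with an intensity trend in the variance. They were also a minority, 48 of 109, when dim signals were raised to the lowest level well above background. After normexp background correction they were 0 of 1 or 13 of 62. Without the filter on dim probes they were 31 of 46, and with a replicate block 30 of 38. The same kind of call made up 25 of 32 without wild type replicate 1, 187 of 239 without wild type replicate 2, 117 of 156 without BnCRY2aOE replicate 1 and 145 of 221 without BnCRY2aOE replicate 2.

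The 4 named probes, chosen by fitted change, were all of this kind. Ranked with bounds in place of stand-in values, A_46_P271793 was number 3 among the higher probes, and the other 3 stayed among the first 2 of their direction. Levels are log2 signal relative to the array's 75th percentile, with SD and n = 2. In the dimmer genotype no array was well above background, so the SD there can be that of stand-in values. The p-values below rest in part on that SD, so they are no measure of the spread between samples in that genotype. Probe A_46_P012171 had a level of 4.38 ± 0.09 in BnCRY2aOE and -5.49 ± 1.07 in wild type, where neither array was well above background, so it was at least 507-fold higher in BnCRY2aOE (adjusted p = 0.014, limma). Probe A_46_P271793 was at 2.61 ± 0.85 in BnCRY2aOE and -6.41 ± 0.11 in wild type, at least 148-fold higher (adjusted p = 0.012, limma). In the other direction, probe A_46_P002941 was at 2.73 ± 0.12 in wild type and -6.91 ± 0.07 in BnCRY2aOE, at least 184-fold lower (adjusted p = 0.0062, limma). Probe A_46_P148134 was at 2.84 ± 0.02 in wild type and -6.04 ± 0.96 in BnCRY2aOE, at least 198-fold lower (adjusted p = 0.014, limma). All 4 kept their direction under every alternative in which they were tested, and all 4 missed the threshold after the planned normexp correction, with adjusted p from 0.0795 to 0.368. Its fit broke down on a few spots, with an estimated background mean of -392 on BnCRY2aOE replicate 2, against 1.26 without marked spots. Without marked spots in the fit, A_46_P012171, A_46_P002941 and A_46_P148134 passed the threshold (adjusted p = 0.0043, 0.0050 and 0.0104, limma). The sizes shrank under normexp, whose offset of 50 lowers the fold of dim signals by construction. The log2 changes of A_46_P012171, A_46_P271793, A_46_P002941 and A_46_P148134 were 5.64, 3.68, -3.46 and -3.40 under the planned correction, and 6.30, 4.24, -4.69 and -4.57 without the spots marked as outlying or non-uniform in its fit, all smaller than the bounds above. Probe A_46_P012171 also missed it without BnCRY2aOE replicate 1 (adjusted p = 0.065, limma), without BnCRY2aOE replicate 2 (adjusted p = 0.055, limma) and without the filter on dim probes (adjusted p = 0.054, limma). Probe A_46_P148134 missed it without wild type replicate 1 (adjusted p = 0.052, limma) and without the filter on dim probes (adjusted p = 0.054, limma), and probe A_46_P271793 after normexp without the marked spots in its fit (adjusted p = 0.088, limma). Over all alternatives the limma adjusted p of A_46_P012171 ran from 0.000624 to 0.0795, of A_46_P271793 from 0.000383 to 0.0876, of A_46_P002941 from 0.000383 to 0.368 and of A_46_P148134 from 0.000453 to 0.368.

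**Figure D2:**
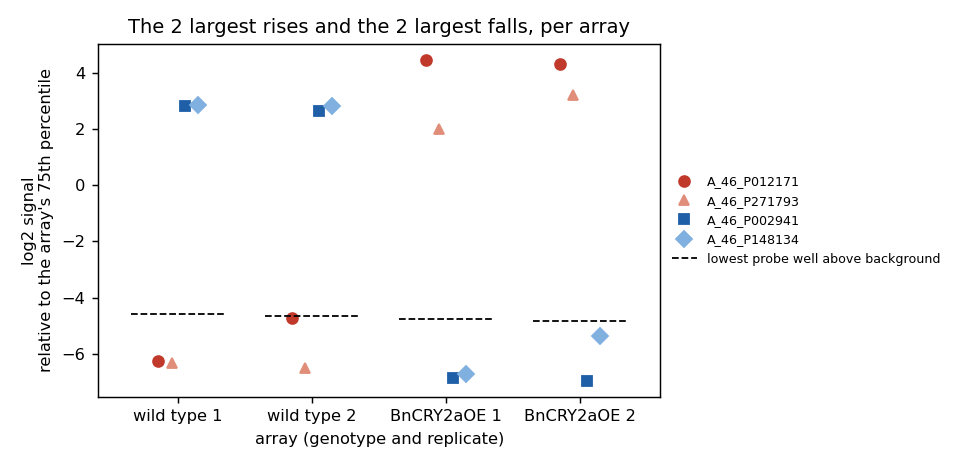
Log2 signal (relative to the array's 75th percentile) of the 4 named probes on each of the 4 arrays; dashed lines mark the lowest level of a probe well above background on that array. Probes A_46_P012171 and A_46_P271793 were at 2.01 or more in both BnCRY2aOE arrays, and A_46_P002941 and A_46_P148134 at 2.65 or more in both wild-type arrays, while each lay below the dashed line in the other genotype.

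Several source sequences are covered by more than 1 probe, which allows their signals to be compared. The 136 calls came from 128 source sequences. Among the 1806 sequences with at least 2 tested probes, 15 held a called probe. In 8 of these every tested probe had a mean change of at least 2-fold in the same direction, 5 upward and 3 downward, and in 6 of the 8 every probe was called. One sequence, which includes A_46_P012171, had a second probe that was higher by 6.60 ± 0.18 (log2, SE). In the other 7 sequences at least 1 probe had a fitted change under 2-fold. In one of the 7 all 3 probes were lower, by log2 changes of -5.52, -1.42 and -0.99, so a limit of 1.9-fold would split the sequences into 9 and 6. In another the called probe had a bound of at least 1.68-fold only. The following 2 were chosen as examples after their values were seen. One had 5 tested probes. Of these, 2 were well above background on 1 of the 2 BnCRY2aOE arrays. With dim signals raised to the lowest level well above background they were 49.3-fold and 33.9-fold lower in BnCRY2aOE; the raising left the second value as fitted. The other 3 had log2 changes of -0.17, 0.04 and 0.03 with SE of 0.18 to 0.35. In the other example, with wild-type levels of 9.04 or more on the log2 scale, 2 probes changed by -5.55 ± 0.18 and -4.12 ± 0.17 (log2, SE) and the third by -0.59 ± 0.17 (adjusted p = 0.63, limma). Leaving aside the most significant call of each sequence, 11 of the 21 other probes had a mean change of at least 2-fold in the same direction (52.4%; probes of 1 sequence are not independent), against 4.55% of all tested probes changed at least 2-fold in either direction. The remaining 10 had a fitted change under 2-fold, and 9 of these were well above background on all 4 arrays.

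**Figure D3:**
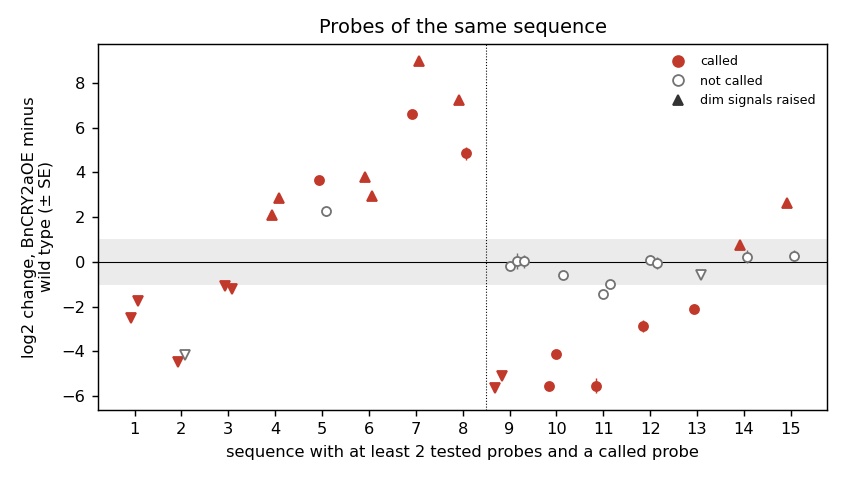
Log2 change (BnCRY2aOE minus wild type) of every tested probe of the 15 sequences that have at least 2 tested probes and a called probe; circles (bars ± SE from limma) were well above background on all 4 arrays, triangles were not and are shown with dim signals raised to the lowest level well above background, filled symbols are called and the grey band marks changes under 2-fold. In the 8 sequences left of the dotted line all probes had changes of at least 2-fold in the same direction, and in the 7 to its right at least 1 probe lay within the band.

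The wild type replicate 1 array stood apart from the other 3 in a set of abundant transcripts, by a criterion chosen after the data were seen. There, 42 probes from 41 sequences lay at least 16-fold below the lowest of the other 3 arrays, on all of which they were well above background and above the 75th percentile. The same criterion found 2 probes on wild type replicate 2, 2 on BnCRY2aOE replicate 1 and 0 on BnCRY2aOE replicate 2. The median gap was 155-fold (7.27 on the log2 scale, range 4.31 to 11.8), and 33 of the 42 were not well above background on wild type replicate 1. The test between the genotypes says nothing about these probes, because the criterion itself sets the wild-type replicates far apart. For all 42 the BnCRY2aOE mean was above wild type replicate 2, by a median of 0.85 on the log2 scale. Without these probes the number of calls was 140, including all 136. The 42 are only a part of the large differences between the wild-type arrays. Over all tested probes, at any level, 96 differed at least 16-fold between the 2 wild-type arrays and 16 between the 2 BnCRY2aOE arrays.

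**Figure D4:**
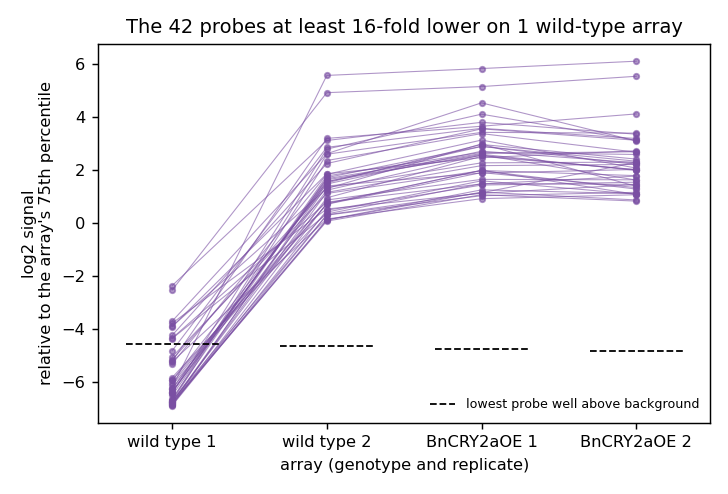
Log2 signal (relative to the array's 75th percentile) on the 4 arrays for the 42 probes that were at least 16-fold lower on wild type replicate 1 than on any other array; each line is a probe and dashed lines mark the lowest level of a probe well above background. Levels on wild type replicate 2 ran from 0.08 to 5.59, and all 42 were higher in the BnCRY2aOE mean.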

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

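The crossed block, spike-in scaling, raised dim signals, normexp without marked spots, its use of median intensity, a limit of 1.9-fold for probes of 1 sequence and removal of the 42 probes low in wild type replicate 1 were chosen after seeing the data. Called probes numbered 136 (all with fitted changes of at least 2-fold), 76 of them with 1 genotype not well above background, of which 13 had bounds under 2-fold. Under quantile or median scaling, the authors' value table, kept outlier spots, a variance trend, robust variance or an adjusted p under 0.1 the count was 112 to 178. These counts changed by over 1.5 times under normexp (1, with 0 in 1 genotype only), normexp without spots marked as outlying or non-uniform (62 and 13), no dim filter (46 and 31), probes well above background on all arrays (32 and, by construction, 0) and a replicate block (38 and 30). With dim signals raised there were 109 and 48. Planned normexp broke down on a few spots whose surroundings outshone them: its estimated background mean was -392 on BnCRY2aOE replicate 2 and 1.26 without marked spots, and the median of all changes moved to 0.32. Leaving out 1 array, with the lone array assumed to vary like the other genotype, gave 32 to 239 calls and 25 to 187 in 1 genotype only; of the 136, 25 remained without wild type replicate 1, 73 without wild type replicate 2, 80 without BnCRY2aOE replicate 1 and 103 without BnCRY2aOE replicate 2. The cause of the other moves was not tested. Same-numbered arrays did not deviate together over the probes (r = -0.16). With a single replicate difference in each genotype, this cannot show whether the numbers pair the samples. A crossed block gave 165 calls. Spike-in scaling moved the median change to 0.17 and gave 179 calls, 94 higher and 85 lower, where the main test had 59 and 77. The gene list tests (camera, fry, estimated correlation, 1 probe per annotation) and cryptochrome probes were not run for lack of gene names, nor slide as a block, since there was 1 slide. Of 15 sequences with several probes, 8 moved together, as with dim signals raised, and 9 with a limit of 1.9-fold. Signal near background limits the fold changes in 1-genotype calls to bounds.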

Other observations

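The tests on probes of 1 sequence, on missing gene copies, on a shared source of RNA and on splits of the arrays were chosen after the results were seen. The tests on stand-in signals and on spot positions were fixed before their results were seen.

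Of the 3 ways to split the 4 arrays into pairs, only the split by genotype gave calls by limma: 136, where the highest of the other splits gave 0, so 1 of the 3 splits reached the real count. At an unadjusted p under 0.05 the other splits gave 339 and 1428 probes against 1903. With 3 splits a share under 0.05 cannot be reached. Each group of the other splits holds both genotypes, so a difference between genotypes widens the spread within it. The counts of those splits therefore do not measure chance.

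The 76 calls with 1 genotype not well above background are 55.9% of all calls. Clustered spot defects under most of these calls are argued against: the median distance to the nearest such spot was 11.7 spot units, at percentile 42.0 of 10000 random sets. The distances pooled calls dim in either genotype, so a cluster in a smaller part of them could be missed. Stand-in values below background are only partly answered, since 63 of the 76 (82.9%, exact 95% interval 72.5% to 90.6%) had bounds of at least 2-fold, and the 13 others did not. Stand-in values as the whole source were set beforehand to leave under 50%, and the interval lies above that. Their exclusion, as set beforehand, asked for at least 80%, which the share of 82.9% met. The interval, which was not part of that rule, reaches below 80%. A difference in expression and a difference in gene content or sequence between the plants of the 2 genotypes both stay open.

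Probes of 1 sequence that do not move together bear on that choice. Every tested probe changed at least 2-fold in the same direction in 8 of the 15 sequences (53.3%, exact 95% interval 26.6% to 78.7%), and in 9 with a limit of 1.9-fold (60.0%, 32.3% to 83.7%). As the only explanation, a change in the level of the whole transcript would move nearly all sequences that way, set at 80% or more. The share cannot decide this, because the interval reaches past 80% with the lower limit. Values within some sequences show that their probes did not change alike. Which transcripts each probe reads was not checked, so a steady probe may read other copies as well. These values therefore cannot decide this either. Leaving aside the most significant call of each sequence, 9 of the 10 probes under 2-fold were well above background on all 4 arrays. In the example with 5 tested probes, 2 fell 49.3-fold and 33.9-fold with dim signals raised. The other 3 had log2 changes of -0.17, 0.04 and 0.03 (SE 0.18 to 0.35). In the other example -5.55 and -4.12 stood beside -0.59. Differences in sequence or gene copy that affect single probes alone would move few, set at 20% or less. The lower end of 26.6% lies above that limit, but the limit was set after the results were seen. The interval also takes the sequences, all read on the same 4 arrays, as independent. In the 8 sequences, a difference under 1 probe alone would not move the others unless probes overlap, which was not checked. The share therefore does not exclude single-probe differences. The share also says nothing against a difference in the copies of a whole gene, which could move all of its probes together. Probe positions were not used here, so overlapping probes, which 1 sequence difference could affect together, and isoforms stay open.

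The 42 probes low on wild type replicate 1 were all higher in the BnCRY2aOE mean than on wild type replicate 2. Spot defects at a place on the slide are argued against for most of the 42, with the median distance to the nearest such spot at percentile 19.8 of random sets. A cluster in a smaller part of them could be missed. The median difference was 0.85 (log2), where 10000 level-matched random sets gave -0.12 to 0.03, but such sets lack the spread that a set varying together has between samples. From the spread of the set between the BnCRY2aOE arrays, whose median differences were 1.00 and 0.77, the 95% interval was -1.67 to 3.45. Gene copies missing from wild type replicate 1 and 1 shared source of RNA scarce in it therefore cannot be told apart, and the SD of the 42 differences, at percentile 14.8 of the random sets, does not decide either. A difference between the genotypes in these probes stays untested.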
